A study of Caulobacter vibrioides with 6 samples.

How the data were processed

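RNA was sequenced from 6 samples of Caulobacter crescentus NA1000, an alphaproteobacterium that is also listed as strain CB15N and as Caulobacter vibrioides. Per the labels' protocols, both strains carried a deletion of vanAB, the genes for vanillate demethylase, together with a plasmid. In 3 samples the plasmid was empty (EV) and in 3 samples it carried the small RNA AbnZ. Cultures grew in PYE medium at 30 °C to an optical density of 0.4 and then received 500 µM vanillate for 15 min, which induces the plasmid promoter. Per the labels' protocols, RNA was extracted with hot phenol, treated with DNase and depleted of ribosomal RNA, and libraries were made with the NEBNext Small RNA kit. The aligner, the counting program, the genome build and whether reads were counted by strand are not given in the sources used here. Nothing states whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

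The authors deposited 1 table of TPM (read counts divided by gene length and scaled to a fixed sum), per the file headers. It lists 4085 genes in 6 columns, and each column sums to 1000000. The column names match the strain number and replicate number of the sample labels, and 0 columns were left unused. The sum includes ribosomal and transfer RNA, which together took 89.6 to 95.1% of TPM, so the TPM of every messenger RNA depends on the ribosomal RNA left in its library.

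Gene names were those of the table. The RefSeq annotation of NA1000 (assembly ASM2200v1) matched 4068 of the 4085 names and supplied symbols, RNA classes, gene lengths and the order of genes. No coordinates are printed because the table names no genome build. For the matched genes, the deposited TPM multiplied by the RefSeq length was a whole multiple of 1 step in every library. Within a tolerance of 0.05, 100% of values came out whole, and the largest deviation was 9e-10. That step was taken as 1 read, which gave 6087038 to 9129045 reads per library. These recovered reads rest on the RefSeq lengths being those the authors used. The 17 unmatched genes have no recovered reads.

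The plan fixed before the data were examined assumed raw counts and a quasi-likelihood count test, with limma on log2(value + 1) where only normalized values were deposited. With TPM, limma was therefore used. That part of the plan named neither a scaling nor a filter for TPM, so both were settled after the unit and the differing composition of AbnZ replicate 1 had been seen. In the course of this, 18 combinations of 3 scalings, 3 filters and 2 pseudocounts were fitted, and the settings described next were kept with the number of genes each combination called in view. Genes with a mean of at least 1 TPM over the 6 libraries entered the test (3139 genes). TPM was scaled between libraries by trimmed means of log ratios (TMM, unweighted, trimming 0.3 of log ratios and 0.05 of levels), the normalization the plan named for counts. The log2(TPM + 1) values were then tested with limma's trend method and robust variance moderation, AbnZ against EV with no other term, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Without any scaling the median log2 fold change of the tested genes was 0.22, against 0.00 with TMM.

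limma-voom, also named in the plan, was run on the recovered reads (the count model), for the 2563 genes with a mean of at least 10 reads, with TMM factors from the reads. The minimum of 10 reads was chosen after the data had been seen. The other count tests planned for raw counts were run neither on TPM nor on the recovered reads. Further alternatives were median-of-ratios scaling, no filter, a filter of at least 50 reads in at least 3 libraries, a replicate block, protein-coding genes only, a pseudocount of 0.1, an adjusted p limit of 0.01, and leaving out each library in turn. TPM without scaling, the other combinations of scaling, filter and pseudocount, a filter on a mean of at least 50 reads, and the alternatives applied to the count model itself, among them no scaling beyond total reads, were added after seeing the data.

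17 gene lists were fixed before the data were examined and matched by gene symbol, the small RNAs by RNA class. CCNA_R0123 was left out of the small RNA list after its values had been seen, because they made it the candidate for the induced RNA. 2 of them, the translocation and assembly module and the TonB-dependent receptors, matched no symbol in the table or annotation and were not analysed here. 13 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The estimated correlation was also applied, after seeing the data, in the settings that called a list. Some genes named in the text follow a rule fixed in advance. It takes called genes whose 3 AbnZ libraries lie beyond all 3 EV libraries (up to 12 in each direction). It also takes up to 4 called members of each list or else its member with the smallest p, and vanA, vanB and vanR. No gene was called lower in the TPM fit, so the same rule was also applied to the count model. That step, and with it every gene named as lower, was chosen after the values had been seen. Further genes are named outside the rule: neighbours of named genes, genes added by an alternative, rodZ, brnT, CCNA_R0196, CCNA_R0005 and CCNA_00696. They were also chosen after their values had been seen. No row of the table or annotation is named AbnZ, tamA or tamB.

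Both fits were tested on simulated reads for the same genes and library sizes, with a set of genes changed by known folds. The changed genes all had real means of at least 10 reads and 1 TPM, and none was ribosomal or transfer RNA. Recovery among tested genes with fewer reads was therefore not measured. Apart from the changed genes, all simulated libraries shared the same composition, so the differing composition of AbnZ replicate 1 was not simulated. Every gene was given the same negative binomial dispersion of 0.0128, a median over genes with many reads. Recovery in the real libraries may therefore be lower. For AbnZ against EV, the TPM fit on 3018 genes recovered 46.9% of 98 genes changed 2-fold and 93.8% of 97 genes changed 4-fold. The count model on 2526 genes recovered 73.6% of 91 and 100% of 89, respectively. Wrong calls numbered 2 and 5. With that many changed genes the adjusted p limit is more lenient than in data in which few genes change.

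All pairs of libraries were compared by a chi-square test of recovered reads over genes. The statistic per degree of freedom was 20.6 to 128.3 within groups and 11.1 to 109.6 between groups, so no pair agreed within sampling noise. Intervals cover counting error only and come from exact (Clopper-Pearson) binomial limits at 95%. For a gene with 0 reads, the limit is the TPM of 3 reads. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.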

Results

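The transcriptome of C. crescentus carrying the AbnZ plasmid was compared with that of the empty-vector strain, with 3 libraries per group, after a 15-min pulse of 500 µM vanillate. The comparison addresses which transcripts differ between the strains soon after the small RNA is induced. No uninduced sample was included, so differences already present before the pulse cannot be told apart. The series title names an essential translocation module as its negatively regulated target, and genes of that module were not matched by symbol and were not analysed here under those names.

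Recovered reads numbered 6519659, 9129045 and 7735903 in the EV replicates 1 to 3 and 6364878, 8331238 and 6087038 in the AbnZ replicates. Most of them came from ribosomal RNA, at 95, 93.3 and 93.4% of reads in EV and 87.1, 94.1 and 94.8% in AbnZ. Protein-coding genes received 120356, 176011 and 160145 reads in EV and 320241, 149246 and 105484 in AbnZ. The protein-coding share was 1.73 to 2.07% in 5 libraries and 5.03% in AbnZ replicate 1, with exact 95% intervals at most 0.04 percentage points wide. The median protein-coding gene had 9 to 33 reads per library. AbnZ replicate 1 accordingly had a median TPM of 7.30 over the tested genes, against 3.31 to 3.84 in the other 5 libraries, and TMM scaling divided its values by 1.80. After scaling, log2 values correlated across genes with Pearson's r of 0.951 to 0.967 within groups and 0.945 to 0.962 between groups. These are correlations over genes, which are not independent replicates.

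The transcript with the smallest limma p between the strains was CCNA_R0123, a non-coding RNA in the RefSeq annotation. Its scaled TPM was 5.19 ± 2.08 (SD, n = 3) in EV and 755 ± 72.4 (SD, n = 3) in AbnZ. It rose by a log2 fold change of 6.98 (SE 0.26, limma adjusted p = 3.62e-06). The libraries held 2, 4 and 6 of its reads in EV and 1429, 553 and 339 in AbnZ. Over the group totals of 12 and 2321 reads, the ratio corrected for TMM-scaled library sizes, which stood at 1.30 for AbnZ over EV, was 148, with an exact 95% interval of 84.7 to 287 that covers counting error only. No row of the table is named AbnZ, so whether CCNA_R0123 is the induced RNA was not established from the names. The nearest tested gene next to it in the annotation, CCNA_00849, had a log2 fold change of 0.23 (SE 0.20, limma adjusted p = 0.939), and the following gene, the efflux pump gene acrB2, had -0.08 (SE 0.19, limma adjusted p = 0.988).

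The second transcript that passed the test was CCNA_01679, a protein-coding gene with no symbol in the annotation. Its scaled TPM rose from 12.7 ± 1.52 (SD, n = 3) in EV to 45.9 ± 10.2 (SD, n = 3) in AbnZ, a log2 fold change of 1.76 (SE 0.21, limma adjusted p = 0.0248). It was higher in 3 of 3 AbnZ libraries than in any EV library. The adjusted p was 0.0605 to 0.171 without any 1 of 5 libraries, namely each EV replicate, AbnZ replicate 1 or AbnZ replicate 3, while the log2 fold change stayed between 1.59 and 1.82. In the count model it was called with every library left out in turn, at limma-voom adjusted p-values of 2.92e-07 to 1.70e-04, but not without scaling beyond total reads (limma-voom adjusted p = 0.115). The genes beside it did not pass the test in either fit. CCNA_01678 had a log2 fold change of -0.32 (SE 0.20) and CCNA_01680 of 0.11 (SE 0.16).

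**Figure D1:**
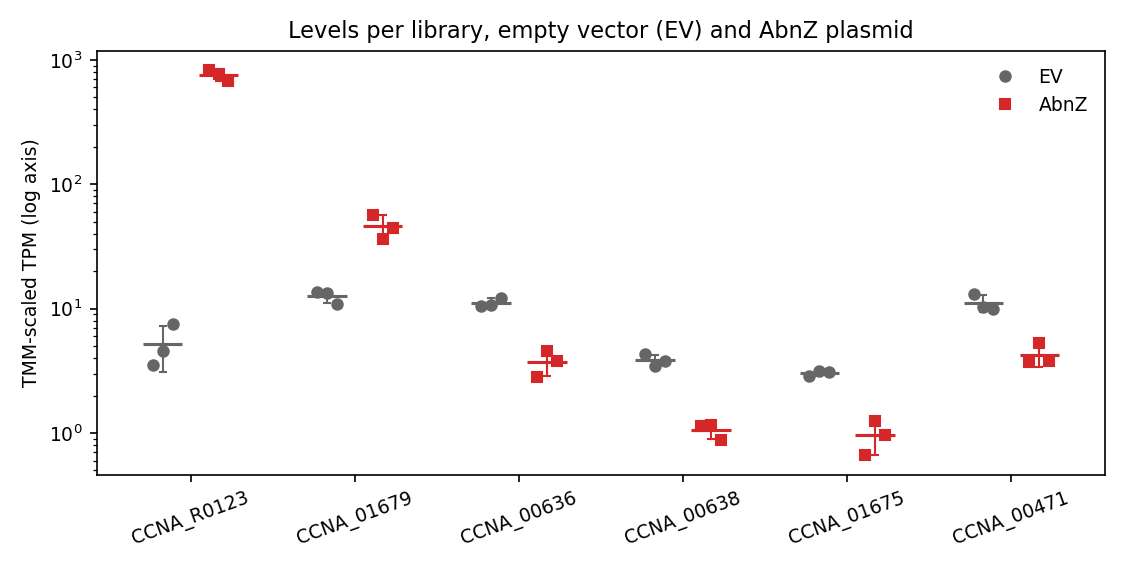
TMM-scaled TPM per library (log axis) of 6 genes, with circles for the 3 EV libraries, squares for the 3 AbnZ libraries, horizontal lines for the group mean and error bars for 1 SD. CCNA_R0123 (5.19 against 755) and CCNA_01679 (12.7 against 45.9) were higher in every AbnZ library than in any EV library, and the other 4 genes, called lower in the count model, were lower in every AbnZ library.

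Across all 3139 genes tested, these 2 genes passed limma's test in the TPM fit, both higher and both by at least 2-fold, and 0 genes were called lower. On TPM without scaling, where the median log2 fold change of all tested genes was 0.22, 4 genes were called, all higher. At an unadjusted p under 0.05 there were 196 genes, 76 higher and 120 lower. Genes whose 3 AbnZ libraries lay outside the range of the 3 EV libraries made up 12.6% of those tested, where chance gives 10%. Both genes were also called in the count model on recovered reads.

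The count model called 25 genes lower in the AbnZ libraries in addition, with log2 fold changes from -1.83 to -0.75 and limma-voom adjusted p-values from 4.85e-05 to 0.0441. In the TPM fit the same 25 genes were lower in 3 of 3 AbnZ libraries and had unadjusted limma p under 0.05. Their limma adjusted p was 0.0601 to 0.696. The recovered reads were computed from the same TPM, so the TPM fit is not separate evidence for these genes. With a stricter filter the TPM fit also called genes lower. There were 18 among those with at least 50 reads in at least 3 libraries, or 0 there without scaling. That filter can admit a gene by the 3 libraries of either group alone, so it can favour genes that fall or genes that rise. With a mean of at least 50 reads over all 6 libraries there were 13. The lower calls depended on the scaling between libraries: without scaling beyond total reads, the count model called 0 genes lower and 1 higher, while all 25 genes kept their sign, with a median of -0.71 against -1.09. The log2 fold changes that follow are from the count model. These genes were chosen for naming after their values were seen. A row of 5 neighbouring protein-coding genes, CCNA_00635 to CCNA_00639, was among them. CCNA_00638 fell by 1.76 on the log2 scale (SE 0.23), from 3.84 ± 0.416 to 1.06 ± 0.158 scaled TPM (SD, n = 3). CCNA_00636 fell by 1.68 (SE 0.24), from 11.1 ± 0.961 to 3.73 ± 0.857 scaled TPM (SD, n = 3). CCNA_00635, CCNA_00637 and CCNA_00639 had log2 fold changes of -1.58, -1.56 and -1.21, with SE of 0.24, 0.27 and 0.26. The chemotaxis genes cheBII and cheRII, which precede this row, had too few reads for the count model, with 5 and 24 reads over the EV libraries and 10 and 26 over the AbnZ libraries.

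The largest fall among the 25 genes was that of CCNA_01675, at -1.83 (SE 0.30, limma-voom adjusted p = 7.06e-04), from 3.05 ± 0.155 to 0.961 ± 0.296 scaled TPM (SD, n = 3). Its neighbour CCNA_01676 fell by 1.14 (SE 0.21, limma-voom adjusted p = 0.00292). Both stand in the gene order just before CCNA_01677 and CCNA_01678, which did not pass (-0.22 and -0.27), and before CCNA_01679, which rose. Another neighbouring pair was CCNA_00471, whose RefSeq symbol is fcl, the name of GDP-fucose synthase, a nucleotide-sugar enzyme, and CCNA_00472. Their log2 fold changes were -1.39 (SE 0.22) and -1.09 (SE 0.21). CCNA_01083 and CCNA_01084, also neighbours, had -1.24 (SE 0.18) and -1.19 (SE 0.24). CCNA_01100 and CCNA_03227 had -1.48 (SE 0.25) and -1.31 (SE 0.25). Of the 25 genes, 3 have a RefSeq symbol, and whether any of the others belongs to the translocation module named in the series title was not determined here. Besides fcl they are CCNA_00893, rodZ, a cell-shape protein of the MreB cytoskeleton, which fell by 0.93 (SE 0.23, limma-voom adjusted p = 0.0435), and brnT, a toxin of a toxin-antitoxin pair, which fell by 0.87 (SE 0.22, limma-voom adjusted p = 0.0441). CCNA_00472, rodZ and brnT lie outside the 12 largest falls that the naming rule takes. The other 10 falls were between -1.06 and -0.75. With each library left out in turn, the count model called 16 to 20 genes lower, and it called 16 without EV replicate 2 and 16 without AbnZ replicate 1.

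**Figure D2:**
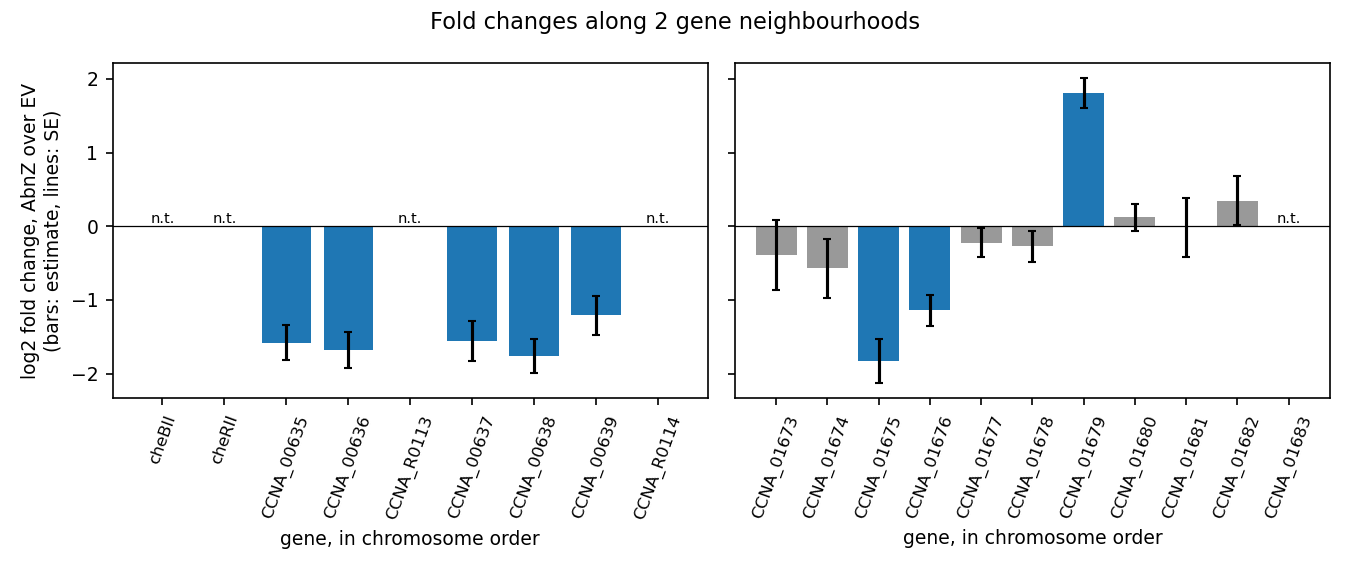
Log2 fold change of AbnZ over EV from limma-voom on recovered reads for genes in chromosome order around CCNA_00635 to CCNA_00639 (left) and CCNA_01675 to CCNA_01679 (right). Bars give the estimate and lines its SE, blue bars passed an adjusted p of 0.05, and n.t. marks genes with too few reads to test. CCNA_00635 to CCNA_00639 lie between -1.76 and -1.21, and CCNA_01675 and CCNA_01679 lie at -1.83 and 1.81.

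**Figure D3:**
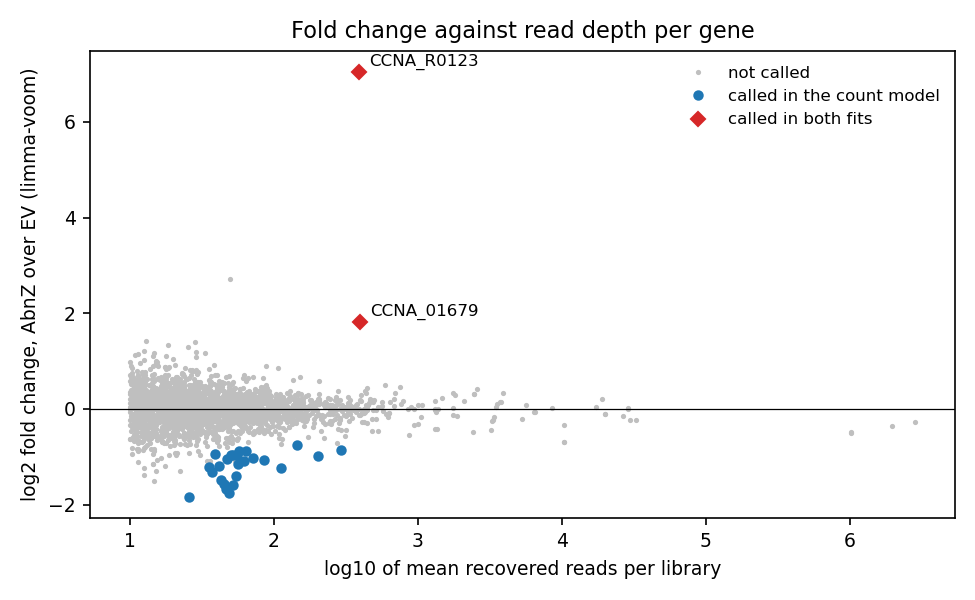
Log2 fold change of AbnZ over EV from limma-voom (y axis) against log10 of the mean recovered reads per library (x axis) for 2504 genes tested in both fits. Diamonds mark the 2 genes called in both fits, circles the 25 genes called lower in the count model alone, and grey points genes that were not called.

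The strain background was read from the vanillate genes. vanA and vanB, the subunits of vanillate demethylase, are deleted in both strains per the labels. vanB had 0, 0 and 0 reads in EV and 1, 1 and 1 reads in AbnZ, all under the limit of 3 reads, which corresponds to 0.328 to 0.598 TPM. vanA was listed with 169, 668 and 473 reads in EV and 1241, 374 and 133 in AbnZ, values that go against the deletion label for vanA in both groups. Whether its reads lie outside the deleted part was not determined here. Its scaled TPM was 55.1 ± 23.5 (SD, n = 3) in EV and 50 ± 22.5 (SD, n = 3) in AbnZ, a log2 fold change of -0.14 (SE 0.42, limma adjusted p = 0.990), but 0.11 on TPM without scaling, 0.14 without EV replicate 2 and 0.24 without AbnZ replicate 3. vanR, the repressor of the vanillate promoter, was at 156 ± 16.3 and 168 ± 23.1 scaled TPM (SD, n = 3), with a log2 fold change of 0.10 (SE 0.22, limma adjusted p = 0.988).

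In the TPM fit none of the 15 gene lists with tested members held a called gene. In the count model none of them held a called gene either. The matching largely fixed this outcome. CCNA_R0123 had been left out of the small RNA list, and CCNA_01679 has no symbol. Of the 25 genes called lower in the count model, 3 have a symbol, and the others could not be matched to a list. The question put to the envelope and surface lists was whether genes of outer membrane assembly, pili, holdfast and flagella moved with AbnZ. For outer membrane protein assembly and envelope transport, 13 genes were tested, with 8 log2 fold changes above 0, 5 below 0 and a median of 0.03. The member with the smallest p was tolA, a subunit of the Tol-Pal envelope complex, at 0.48 (SE 0.23, limma adjusted p = 0.808). For pilus and holdfast, 30 genes were tested and split 15 above and 15 below 0, and the smallest p was that of hfsL (CCNA_02360), a holdfast synthesis gene, at 0.45 (SE 0.21). For flagellum and chemotaxis, 39 of 56 tested genes had log2 fold changes below 0, with a median of -0.11. limma's camera gave this list an adjusted p = 0.304. cheYI, a chemotaxis response regulator, had -0.48 (SE 0.21). For peptidoglycan and lipid A synthesis, 20 genes were tested with a median of -0.07, and ldpA (CCNA_01948), a member of the LytM-domain protein family, had the smallest p, at -0.76 (SE 0.19, limma adjusted p = 0.306). Adjusted over the list alone, 0 genes of this list were called in the TPM fit and 1, ldpA, in the count model.

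Among regulatory lists, the 45 tested cell cycle and division genes had a median log2 fold change of -0.05. The smallest p was that of cpdR, a response regulator that controls proteolysis by ClpXP, at 0.66 (SE 0.17, limma adjusted p = 0.407). The RNA decay and small RNA machinery list had 5 tested genes. Of these, hfq (CCNA_01819), the RNA chaperone that many small RNAs need, had a log2 fold change of -0.75 (SE 0.20), from 20.3 ± 1.81 to 11.8 ± 2.91 scaled TPM (SD, n = 3). Its limma adjusted p was 0.407 over all genes, and adjusted over the list alone 1 gene of this list, hfq, was called, as in the count model. The alternative sigma factor and general stress list had 10 of 13 genes below 0 and a median of -0.11. Its camera test gave an adjusted p = 0.304 in limma and an adjusted p = 0.778 with an estimated correlation. Its smallest p was that of lovK, a blue-light sensor kinase, at -0.64 (SE 0.25).

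The 111 small RNAs tested besides CCNA_R0123 had a median log2 fold change of 0.12, with 66 above and 45 below 0. Their camera test gave an adjusted p = 0.304 in limma and an adjusted p = 0.778 with an estimated correlation. In limma's camera the list was called on TPM without scaling (adjusted p = 0.00263) and without AbnZ replicate 3 (adjusted p = 0.0344). With an estimated correlation limma's camera called it in neither (adjusted p = 0.972 and adjusted p = 0.879). The smallest p was that of CCNA_R0158, at 1.16 (SE 0.21, limma adjusted p = 0.129), from 8.29 ± 2.18 to 19.3 ± 1.79 scaled TPM (SD, n = 3), and adjusted over the list alone it was the 1 gene called. In the count model 0 of the 60 small RNAs tested were called adjusted over the list alone, and CCNA_R0158 had a limma-voom adjusted p = 0.436 over all genes. Its reads numbered 3, 8 and 6 in EV and 31, 11 and 9 in AbnZ. The carbon-starvation small RNA crfA, the single tested member of the iron and zinc list, had -0.35 (SE 0.23).

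The housekeeping lists had medians between -0.04 and 0.14. The 26 ribosomal protein genes had a median of -0.01, with rpsN at 0.46 (SE 0.26), and limma's camera called the list higher without AbnZ replicate 1 (adjusted p = 0.0232), but not with an estimated correlation (adjusted p = 0.632). The 19 respiration and ATP synthesis genes had 0.06, with nuoJ, a subunit of respiratory complex I, at 0.32 (SE 0.17). The 12 heat shock genes had -0.04, and the adaptor of the ClpAP protease, clpS, was at 0.62 (SE 0.39). The 12 SOS genes had -0.01, and imuB, a component of the mutagenic repair polymerase, was at -0.45 (SE 0.20). The 7 central carbon genes had 0.14, with pgl at 0.32 (SE 0.25). For the 13 lists tested, limma's camera and fry called 0 at an adjusted p of 0.05, and the smallest adjusted p was 0.304, 0.778 with an estimated correlation and 0.574 in fry. Before adjustment, 2 lists, stress and small RNAs, were under 0.05 in camera, and 1, stress, in fry. fry's mixed test, which asks whether genes change in either direction and does not compare them with other genes, was under 0.05 before adjustment for 2 lists, cell cycle and RNA decay.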

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

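TPM without scaling, the combined settings, the mean of at least 50 reads, the estimated correlation in the settings that called a list, and all alternatives to the count model were chosen after the result was seen. Running limma-voom on recovered reads, rather than on raw counts, was decided after the unit had been seen. The count of 2 called genes, and of 2 at least 2-fold, stayed at 2 with median-of-ratios scaling, no filter and a pseudocount of 0.1. It was 27 (2 higher, 25 lower) and 18 at least 2-fold in limma-voom on recovered reads, and 20 (2 higher, 18 lower) and 8 at least 2-fold with at least 50 reads in at least 3 libraries, where 844 genes were tested. That filter can admit a gene by the 3 libraries of either group alone. With a mean of at least 50 reads over all 6 libraries (900 genes), 15 were called (2 higher, 13 lower), 5 at least 2-fold. It was 1 with the replicate block, 1 with protein-coding genes only, which leaves out CCNA_R0123 by construction, and 1 at an adjusted p of 0.01. It was 4, all higher, on TPM without scaling, where CCNA_01973 and CCNA_R0187 were added. Of the 18 combinations of scaling, filter and pseudocount, those with TMM or median-of-ratios scaling called 2 genes with a mean TPM filter or no filter, and 18 to 20 (8 or 11 at least 2-fold) with at least 50 reads in at least 3 libraries: 19 at a pseudocount of 0.1 with TMM, and 19 and 18 at pseudocounts of 1 and 0.1 with median-of-ratios scaling. Those without scaling called 2 to 9, all higher and at least 2-fold: 3 with the mean TPM filter at 0.1, 9 and 4 with no filter at 1 and 0.1, and 2, 0 of them lower, with at least 50 reads in at least 3 libraries. Without 1 library it ranged from 1 to 2. Where a single choice was changed, CCNA_R0123 was called in each setting that tested it, with log2 fold changes of 6.79 to 7.24. Replicate numbers did not pair the libraries, with correlations of deviations at equal numbers of -0.02, -0.01 and 0.04, and 1 of 3 EV libraries correlated best with its own number. The replicate block took the adjusted p of CCNA_01679 to 0.207. In the count model, 20 genes were lower with the replicate block, 25 with median-of-ratios scaling, 26 with protein-coding genes only, 17 with at least 50 reads in at least 3 libraries, 14 with a mean of at least 50 reads, 15 at an adjusted p of 0.01 and 0 without scaling beyond total reads, where CCNA_01679 was not called. Without 1 library, 16 to 20 were lower. Gene lists called numbered 0 in the main test, in the count model, with the replicate block, with an estimated correlation and in fry. TPM without scaling called 1 (small RNAs). Leaving out a library gave 0 to 1, ribosomal proteins without AbnZ replicate 1 and small RNAs without AbnZ replicate 3. With an estimated correlation each of these 3 settings called 0. Of 43 named genes, 2 changed sign: vanA was at 0.11 on TPM without scaling, 0.14 without EV replicate 2 and -0.52 to 0.24 without 1 library, and vanR was at 0.00 to 0.20 without 1 library. The cause was not tested for these changes. The 25 lower genes had 156 to 1758 reads in all 6 libraries together. The planned count tests other than limma-voom were run neither on TPM nor on the recovered reads.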

Other observations

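The tests of neighbouring genes, of AbnZ replicate 1, of CCNA_R0123 and of CCNA_01679 were chosen only after the result was seen. The genes that were lower in the count model lay next to one another more often than chance placed them. The 25 genes held 7 pairs of neighbouring protein-coding genes. Against these, 10000 random sets of genes matched on mean reads held 0.23 pairs on average and 3 at most. The pairs formed 4 runs of 11 genes: CCNA_00635 to CCNA_00639, CCNA_00471 with CCNA_00472, CCNA_01083 with CCNA_01084, and CCNA_01675 with CCNA_01676. In the 18 lists of equal length from the other splits of the libraries there were 0 to 2 pairs, and 0 among the top rising genes of the real split. What these neighbours have in common was not tested, as neither strand nor operon data were used here.

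These falls may have technical sources as well. The falls did not rest on AbnZ replicate 1 alone, the library with the most protein-coding reads. Without it, the 25 genes had a median log2 fold change of -1.10, against -1.09 (SD 0.31 over genes) with it. All 25 kept their sign and 14 their call. A composition effect stays open. The genes were chosen as lower in these same libraries, and the refit was again scaled by TMM. The calls themselves depend on correcting for library composition, since 0 genes were called lower in the count model without scaling beyond total reads. The lower genes were longer (median 1626 bp against 903 bp over the tested genes). Their median was -1.10 after a trend on length was taken off, so a trend shared by all tested genes does not account for its size. Whether greater length made these genes easier to call was not tested. The 6 libraries form 10 splits of 3 and 3, too few for a share under 0.05. In the count model the real split called 27 genes and the highest other split 0. In the TPM fit the real split called 2 genes, both at least 2-fold, and the highest other split 1.

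CCNA_R0123 is a candidate for the AbnZ RNA itself, as a hypothesis. A single swapped or mislabelled library would have put an AbnZ library in the EV range. The lowest AbnZ library was instead 90.3 times the highest EV library in scaled TPM. This separation had been seen beforehand, and it cannot show an exchange of the whole groups. Transcription running through the chromosomal locus would have raised a neighbour. CCNA_00849 on one side had a log2 fold change of 0.23 (SE 0.20), and CCNA_00848 on the other had 1, 0 and 2 reads in EV and 1, 0 and 1 in AbnZ. The strand of these genes was not used here. The largest log2 fold change among the other 111 non-coding RNAs tested was 1.93 (SE 0.89), for CCNA_R0196. The plasmid sequence was not used here, so the identity stays open.

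CCNA_01679 rose while the genes beside it did not pass the test. A rise in AbnZ replicate 1 alone is argued against, since the log2 fold change was 1.59 without that library. A rise of the whole neighbourhood is argued against, since the median log2 fold change of the 2 genes on each side was -0.18. A biological effect of AbnZ on this transcript and reads of a plasmid-borne or near-identical sequence both stay open, as neither was tested.

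CCNA_00696, chosen because its reads lay almost wholly in AbnZ replicate 1, had 4, 3 and 2 reads in the EV libraries and 286, 3 and 0 in the AbnZ libraries, and its limma-voom adjusted p was 0.879. The signal recognition particle RNA (CCNA_R0005) took 16800, 16700 and 32200 TPM in EV and 41500, 19600 and 26900 TPM in AbnZ. These values are not scaled between libraries, and with TMM scaling its log2 fold change was 0.17.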
